A study of Medicago truncatula with 23 samples.

How the data were processed

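The series holds RNA sequencing of 23 Medicago truncatula libraries in 6 groups. Hairy roots carried the NIN gene under a ubiquitin promoter of Lotus japonicus (NINox, 4 libraries) or GFP under the same promoter (GFP, 3 libraries). Per the labels, these roots formed without rhizobia and were collected after 3 weeks. Nodules were collected 15 days after inoculation with Sinorhizobium meliloti. They came from the wild types A17 and R108, from dnf1-2 in the A17 background and from nin-16 in the R108 background, with 4 libraries each. Groups and replicate numbers were taken from the sample titles. The genotype label of the GFP libraries names the NIN construct while their titles name GFP, and the titles were used. The labels do not say whether replicates came from separate plants, so p-values measure only the spread between these libraries.

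Per the labels' protocols, RNA was extracted from roots and from nodules with different kits, and libraries were prepared with a stranded mRNA kit. Per the submitters' processing notes, FastQC, STAR and featureCounts were used, and their versions and the genome build are not given in the sources used here. The authors deposited FPKM values, that is fragments per kilobase of gene and per 1 M reads, in 2 tables, 1 for roots and 1 for nodules. In both tables each value was scaled by its gene's length and its own library's total only. Every fit stayed within a table, while the nodule-restricted sets and the overlaps with NINox calls joined both. Any level set across roots and nodules also carries the difference in extraction. All columns were assigned to a sample. Each table lists 50894 gene ids without names.

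The deposited FPKM values are whole multiples of the value of 1 read, which gave each library's total and each gene's length. With these lengths, 100% of the 652687 values above 0 came out as whole reads within 0.01 read, which follows in part from how the lengths were found. Independently of this, the recovered reads of each library summed to its total with at most 124 reads missing. Library totals were 16.1 to 31.5 M reads with a median of 19.4 M, so 1 read in a gene of 1 kb was worth 0.0318 to 0.062 FPKM. Replicates were compared before averaging. The chi-square of recovered reads per degree of freedom was 4.94 to 127 over the replicate pairs, so no pair agreed within sampling noise.

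Comparisons were NINox against GFP, dnf1-2 against A17, nin-16 against R108, the dnf1-2 effect against the nin-16 effect, and R108 against A17. Each was tested with limma-trend (limma 3.58.1 in R 4.3.3) on log2(FPKM + 1), 2-sided, with Benjamini-Hochberg adjustment and calls at an adjusted p under 0.05. The 7 root libraries formed 1 fit and the 16 nodule libraries another, in which the 4 nodule groups shared 1 estimate of the spread. Genes were kept at 1 FPKM or more in at least 3 root or 4 nodule libraries. Fold changes are differences on the log2(FPKM + 1) scale, which understates changes of low genes, and SE is the standard error of that difference. Equal folds from unequal base levels also look unequal on this scale, which affects the comparison of the 2 mutant effects. Recovery and tables were computed with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots with matplotlib 3.10.9.

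Gene lists were fixed before the data were examined. Because the tables hold no gene names and 0 of their ids matched the reference table, 24 lists that select genes by product text could not be used. Used here were 3 lists of 45 ids: symbiotic signalling and infection (22), nodule organogenesis regulators (13), and bacteroid differentiation and persistence (10). Each id was paired with its published symbol from memory, and no annotation used here could check these pairs. A list of 11 ids taken as leghemoglobins was added after the data were seen, in the same way. Its members may be similar copies that share reads, which was not checked, so single members are uncertain. The text names NIN and DNF1 in every group, the genes of these lists, and at most 2 unnamed ids per direction and comparison with the largest change and no overlap between groups. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated from the data.

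A set of nodule-restricted genes was defined after the data were seen, as genes under 0.5 FPKM in every GFP library and at 10 FPKM or more in every library of a wild type. For dnf1-2 the wild type was R108 and for nin-16 it was A17, so the control libraries of a test did not choose its genes. The 798 genes that met these limits in both wild types were used for shares, for the NINox roots and to set the mutants side by side, where the controls did take part in the choice. Overlaps of calls were tested with Fisher's exact test. The nodule mutants share no library, so no allowance for shared controls was made.

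The tests were tried on simulated data drawn from the real means and spreads, with 200 genes changed. Of genes changed 2-fold, 78% were recovered for NINox against GFP, 68% for dnf1-2 against A17, 60% for nin-16 against R108, 50% for the difference of the 2 mutant effects and 48% for R108 against A17. Of unchanged genes, 8, 39, 14 and 11 were called for NINox, dnf1-2, nin-16 and R108, in that order. These made up 4.8%, 21.8%, 9.2% and 8% of the simulated calls, so in the draw run for each comparison all but NINox exceeded the share that the adjustment allows. Only 200 genes were changed, far fewer than were called in the real data. Neither these shares nor those below are therefore the false shares of the real calls. For the difference of effects, 782 of 23303 genes with equal folds in both backgrounds were called when equality was set on the FPKM scale (85.9% of the simulated calls). When it was set on the tested scale 234 were called (65.4%), of which 206 were held at 0 in a group.

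Replicate numbers are shared across groups, and it was checked whether libraries with the same number deviate together from their group means. Between R108 and nin-16 the correlations across genes were 0.61, 0.35, 0.50 and 0.53, and each nin-16 library matched its own number best, so a pairing was taken from the data alone. The fits that give the reported counts carry no block, and a fit with the replicate number as a block was run beside each. Other alternatives set before the data were examined were a pseudocount of 0.1, no filter and a filter at 5 FPKM, quantile normalization, median ratio rescaling, array weights, fits on the groups compared only, a minimum change of 2-fold, and leaving out each library in turn. Alternatives added after the data were seen were voom on the recovered reads, a replicate block within each background, genes expressed in both backgrounds, lists without the targeted gene, list tests without a filter, other limits for the nodule-restricted set, and leghemoglobins and nodule-restricted genes without dnf1-2 replicate 3. An exploratory fit with the settings fixed earlier was run before the final analysis was written.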

Results

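Transcript levels were measured by RNA sequencing in hairy roots that overexpress NIN or GFP and in nodules of 2 wild types and 2 mutants of Medicago truncatula. There were 4 NINox and 3 GFP root libraries, and 4 nodule libraries each of the wild types A17 and R108 and of the mutants nin-16 and dnf1-2, with 16.1 to 31.5 M reads per library. Summed FPKM differed between nodule groups, at 861383 to 933988 in A17 and 859830 to 891424 in R108 but 665864 to 695351 in dnf1-2 and 670064 to 691902 in nin-16. Root libraries summed to 580165 to 586389.

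NIN and DNF1, the genes that the construct and the mutants target, were examined first. NIN (Medtr5g099060), the transcription factor that starts nodule formation, stood at 0.249 ± 0.0335 FPKM (SD, n = 3) in GFP roots and at 159 ± 28.1 FPKM (SD, n = 4) in NINox roots. Reads of the construct and of the plant's own NIN cannot be separated in these values. In nodules, NIN stood at 92.2 ± 26.6 FPKM in A17, 56.4 ± 16.1 in dnf1-2, 78.6 ± 10.1 in R108 and 58.2 ± 2.45 in nin-16 (SD, n = 4 each). The labels do not say how nin-16 affects the NIN transcript, so its level in nin-16 does not show how much working NIN remains. DNF1 (Medtr3g027890), a subunit of the signal peptidase complex of the nodule secretory pathway, stood at 240 ± 20.1 FPKM in A17 (SD, n = 4). The dnf1-2 libraries held 12.9, 11.4, 75.4 and 13.5 FPKM of DNF1, so replicate 3 was above the other 3 and below every A17 library. DNF1 stood at 439 ± 57.2 FPKM in R108 and 974 ± 169 FPKM in nin-16 (SD, n = 4 each), and at 51.6 ± 3.45 FPKM in NINox and 40.8 ± 1.75 FPKM in GFP roots.

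**Figure D1:**
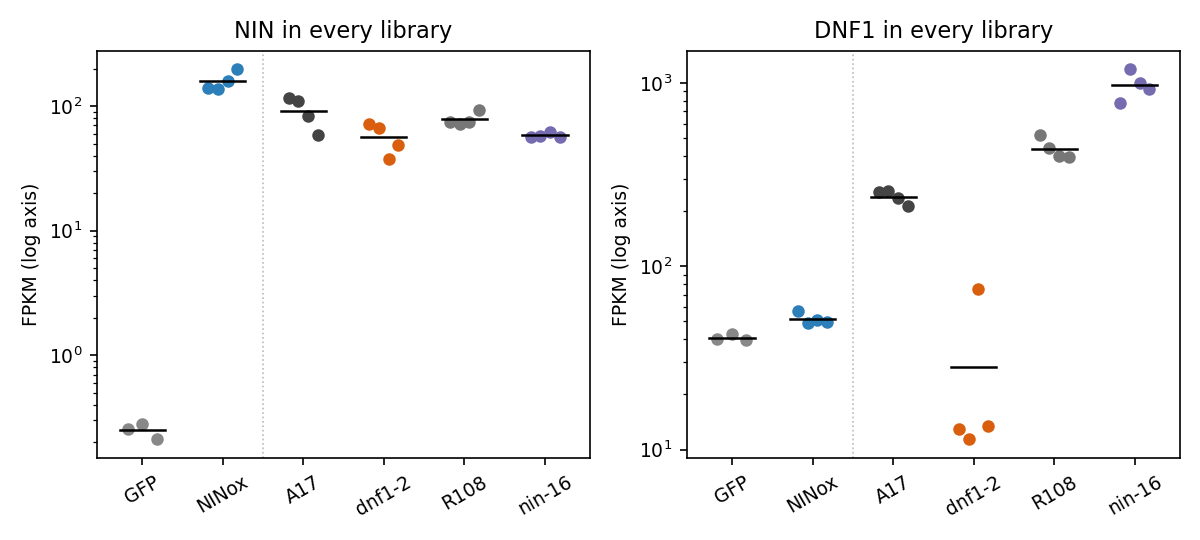
Levels of NIN (left) and DNF1 (right) in FPKM on a log axis, with a point per library, a line at each group mean, and a dotted line between the root and nodule tables. NIN averaged 159 FPKM in NINox roots and 0.249 in GFP roots, and replicate 3 of dnf1-2 held 75.4 FPKM of DNF1.

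Genes that respond to NIN in roots grown without rhizobia were sought first. NF-YA1 (Medtr1g056530), a CCAAT-binding factor of the nodule meristem, rose from 0.109 ± 0.049 FPKM (SD, n = 3) in GFP to 5.82 ± 2.31 FPKM (SD, n = 4) in NINox roots. CLE13 (Medtr4g079610), a peptide that restrains nodule number, was listed at 0 in all 3 GFP libraries and at 2.51 ± 1.75 FPKM (SD, n = 4) in NINox. SYMREM1 (Medtr8g097320), a remorin of infection threads, rose from 0.0952 ± 0.0597 to 5.54 ± 3.22 FPKM. SYMCRK (Medtr3g079850), a receptor-like kinase needed for bacteroid persistence, rose from 0.0255 ± 0.025 to 2.53 ± 1.19 FPKM. FLOT4 (Medtr3g106430), a flotillin of the infection process, fell from 34.2 ± 10.5 to 17.9 ± 3.47 FPKM.

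Of the 12 tested nodule organogenesis regulators, 6 were higher in NINox roots, 0 were lower and 6 did not pass (7 higher and 0 lower adjusted over the list alone). NIN rose by 6.98 (SE 0.12, limma adjusted p = 4.2e-08), NF-YA1 by 2.55 (SE 0.27, limma adjusted p = 0.00078) and NLP1 (Medtr3g115400), a NIN-like factor of the nitrate response, by 0.67 (SE 0.08, limma adjusted p = 0.0013). The others were CLE13, LBD16 (Medtr7g096530), a factor of lateral root founding, and NOOT2 (Medtr1g051025), a regulator of nodule identity. As a list they ranked higher than other genes (camera adjusted p = 0.0015, and 0.017 without NIN), but not with an estimated correlation (adjusted p = 0.13). NIN, NF-YA1 and CLE13 reached the filter only through the NINox libraries, as did SYMREM1, VPY, LYK10, SYMCRK and DNF2 of the other lists, so that their own change let them into these counts and tests. Without a filter, where no change decides which members are tested, the list also passed (camera adjusted p = 0.00029). NIN, raised by the construct, was still in that list, and a value without both the filter and NIN was not computed. Of the 16 tested signalling and infection genes, 6 were higher, FLOT4 was lower and 9 did not pass (7 and 2 adjusted over the list alone). SYMREM1 rose by 2.42 (SE 0.38, limma adjusted p = 0.0029), the vapyrin VPY (Medtr6g027840), needed for infection threads, by 1.17 (SE 0.18, limma adjusted p = 0.0029), the LysM receptor kinase LYK10 (Medtr5g033490) by 1.06 (SE 0.23, limma adjusted p = 0.0099) and the receptor kinase DMI2 (Medtr5g030920) by 0.33 (SE 0.07, limma adjusted p = 0.01). This list did not pass (camera adjusted p = 0.055, and adjusted p = 0.2 with an estimated correlation). It passed with a pseudocount of 0.1 (camera adjusted p = 0.046), with median ratio rescaling (camera adjusted p = 0.043), without a filter (camera adjusted p = 0.0056) and without NINox replicate 2 or 3 or GFP replicate 2 (camera adjusted p = 0.049, 0.015 and 0.045).

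Of the 7 tested bacteroid genes, SYMCRK, DNF2 (Medtr4g085800), a phospholipase C-like protein that holds back defence, and DNF1 were higher in NINox, by 1.72, 1.49 and 0.33 (limma adjusted p = 0.0026, 0.0062 and 0.0068). DME (Medtr1g492760), a DNA demethylase that reached the filter only through the GFP libraries, was lower and 3 did not pass (3 and 1 adjusted over the list alone; camera adjusted p = 0.39, and adjusted p = 0.55 with an estimated correlation). Of 11 leghemoglobins, the oxygen carriers of the infected cell, 8 were too low to be tested. The 3 others reached the filter only through the NINox libraries, so that their rises were fixed by the choice of genes and no list test is given. They were Medtr5g066070 (2.29 FPKM in NINox, listed at 0 in GFP), Medtr1g090810 (2 against 0.0821 FPKM) and Medtr1g090820 (2.15 against 0.751 FPKM). Across all 21868 genes tested, 3918 were higher and 2747 lower, of which 361 and 379 changed at least 2-fold. With median ratio rescaling 49.8% of calls were higher, against 58.8%. Among unnamed ids, those with the largest rises were Medtr4g059837 (6.73, listed at 0 in GFP) and Medtr3g055450 (6.22), and those with the largest falls were Medtr2g438540 (-5.35) and Medtr2g438560 (-5.30). The tables do not pair these ids with names.

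The count of calls in NINox fell to 3861 without GFP replicate 2, 4408 without GFP replicate 3 and 4456 without GFP replicate 1, against 6665. The call for NSP1 (Medtr8g020840, 0.47) ended without any 1 library other than NINox replicate 3 (limma adjusted p = 0.069 to 0.14), without a filter (limma adjusted p = 0.077) and with quantile normalization (limma adjusted p = 0.073) or median ratio rescaling (limma adjusted p = 0.053). LIN (Medtr1g090320, 0.27) ended without NINox replicate 1 (limma adjusted p = 0.063) or GFP replicate 1, 2 or 3 (limma adjusted p = 0.055, 0.09 and 0.058). LBD16 (0.63) ended without NINox replicate 1 or 2 (limma adjusted p = 0.064 for each), GFP replicate 1 or 2 (limma adjusted p = 0.089 and 0.057), without a filter or with the replicate block (limma adjusted p = 0.05 for each). FLOT4 (-0.87) ended without GFP replicate 2 (limma adjusted p = 0.052).

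Nodule-restricted genes were also detectable in NINox roots. Of the 798 genes near 0 in GFP roots and abundant in nodules of both wild types, 66 reached 1 FPKM in all 4 NINox libraries, against 2 of 10117 genes low in GFP roots and in both wild types (Fisher's exact test, 2-sided p = 1.6e-73). These limits were set across roots and nodules, whose RNA was extracted with different kits. The 10117 genes were low in GFP, A17 and R108 alike, so many may hardly be expressed in any sample. The test therefore does not show that NIN favours nodule genes, and its p-value treats genes as independent. The count was 134 without NINox replicate 3 and 66 to 68 without any other NINox library. The 798 genes made up 0.22 ± 0.11% of summed FPKM in NINox roots and 40.42 ± 3.59% in A17 nodules (SD, n = 4 each). NIN itself is among the 798 genes and among the 66, so construct reads are part of the NINox share.

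Nodules of dnf1-2, whose bacteroids do not mature, were then set against A17. Leghemoglobins fell from 3.96 ± 0.39% of summed FPKM in A17 to 0.26 ± 0.28% in dnf1-2 (SD, n = 4 each). NCR169 (Medtr7g029760), a nodule-specific cysteine-rich peptide required for bacteroid differentiation, fell from 1110 ± 174 to 43.7 ± 49.2 FPKM. NLP2 (Medtr4g068000), a NIN-like factor that activates leghemoglobin genes, fell from 137 ± 14.7 to 4.06 ± 4.51 FPKM. The 798 nodule-restricted genes fell from 40.42 ± 3.59% to 9.98 ± 1.48% of summed FPKM. Replicate 3 of dnf1-2 was highest for leghemoglobins (0.68%, against a mean of 0.117% in the other 3 libraries), NCR169 (117 FPKM) and NLP2 (10.8 FPKM).

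**Figure D2:**
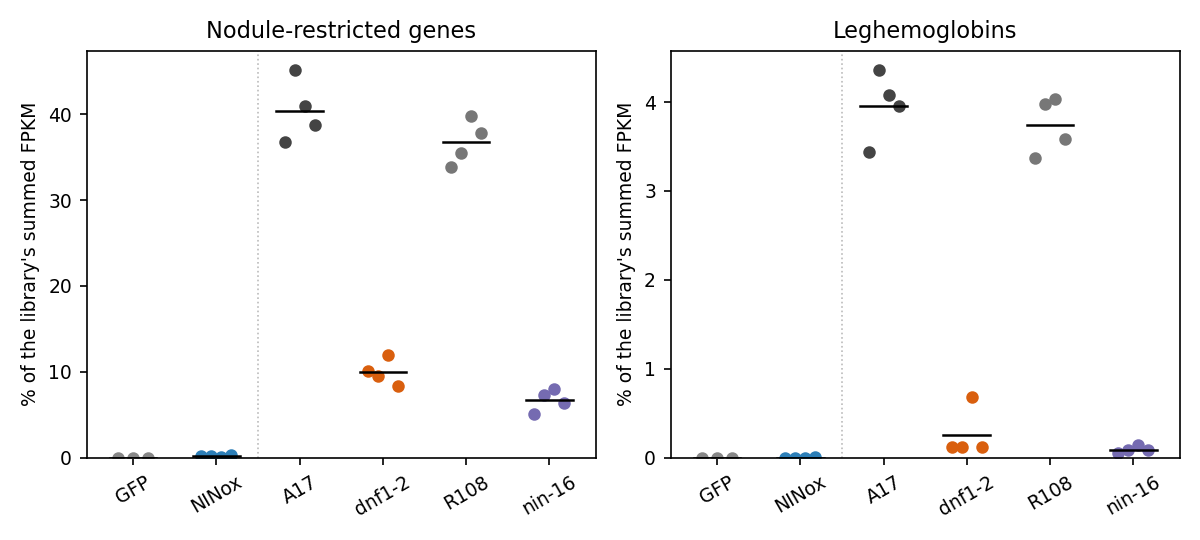
Percent of each library's summed FPKM held by the 798 nodule-restricted genes (left) and the 11 leghemoglobins (right), with a point per library and a line at each group mean. Leghemoglobins averaged 3.96% in A17 and 3.75% in R108, against 0.26% in dnf1-2 and 0.09% in nin-16, and replicate 3 of dnf1-2 lies above its group at 0.68%.

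All 11 leghemoglobins fell, with a median of -5.14, and -5.99 without dnf1-2 replicate 3 (camera adjusted p = 1.3e-14, and adjusted p = 0.024 with an estimated correlation). The smallest fall was that of Medtr1g090810 (-0.53), which ended with quantile normalization (limma adjusted p = 0.13) and without A17 replicate 3 or 4 or dnf1-2 replicate 2, 3 or 4 (limma adjusted p = 0.056 to 0.099). Of the 9 tested bacteroid genes, 7 fell, LATD rose and 1 did not pass (7 and 1 adjusted over the list alone; camera adjusted p = 3.1e-06, and adjusted p = 0.0054 with an estimated correlation). NCR169 fell by 5.16 (SE 0.48, limma adjusted p = 9e-07) and DNF1 fell by 3.52 (SE 0.42, limma adjusted p = 1.1e-05). NAD1 (Medtr7g022640), which holds back defence after bacterial release, fell by 1.96 (SE 0.21, limma adjusted p = 4.1e-06) and SYMCRK fell by 1.68 (SE 0.22, limma adjusted p = 3.4e-05). The fall of DNF2 ended with quantile normalization (-0.3, limma adjusted p = 0.1). The nitrate transporter LATD (Medtr1g009200) rose by 1.61 (SE 0.20, limma adjusted p = 2.4e-05). Without dnf1-2 replicate 3, the DNF1 mean was 12.6 FPKM, and the falls of DNF1, NCR169 and NLP2 were -4.15, -5.81 and -5.61.

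Of the 12 tested organogenesis regulators, 5 fell, 3 rose and 4 did not pass (5 and 3 adjusted over the list alone; camera adjusted p = 0.0097, and adjusted p = 0.14 with an estimated correlation). NLP2 fell by 5.09 (SE 0.38, limma adjusted p = 1.3e-07), CLE13 fell by 2.65 (SE 0.44, limma adjusted p = 0.00026) and the cytokinin receptor CRE1 (Medtr8g106150) fell by 0.83 (SE 0.22, limma adjusted p = 0.0088). NIN fell by 0.70 (SE 0.21, limma adjusted p = 0.018), with overlap between the groups. That call ended in a fit of the 2 groups alone (limma adjusted p = 0.077) and without A17 replicate 1 or 2 or dnf1-2 replicate 3 or 4 (limma adjusted p = 0.05 to 0.063). NF-YA1 stood at 182 ± 64.4 FPKM in dnf1-2 and 163 ± 41.4 in A17 and did not pass (0.12, limma adjusted p = 0.75), but did with array weights (0.47, limma adjusted p = 0.048). Of the 22 signalling and infection genes, 8 fell, 2 rose and 12 did not pass (8 and 2 adjusted over the list alone; camera adjusted p = 5e-04, and adjusted p = 0.14 with an estimated correlation). IPD3 (Medtr5g026850), the transcription factor that activates NIN, fell by 1.66 (SE 0.19, limma adjusted p = 7e-06), and ERN1 (Medtr7g085810), an ERF factor of infection, fell by 0.93 (SE 0.15, limma adjusted p = 0.00024). DMI3 (Medtr8g043970), the calcium- and calmodulin-dependent kinase upstream of IPD3, fell by 0.84 (SE 0.19, limma adjusted p = 0.0031). FLOT4 rose by 1.14 (SE 0.24, limma adjusted p = 0.0019), and SYMREM1 stood at 279 ± 40.9 FPKM in dnf1-2 and 302 ± 15.3 in A17 without passing (limma adjusted p = 0.52).

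Of the 1020 nodule-restricted genes tested, 716 fell, 21 rose and 283 did not pass, with a median of -1.93 (camera adjusted p = 5.6e-87, and adjusted p = 0.002 with an estimated correlation). Across all 23450 genes, 7036 were called higher and 2302 lower, so that 75.3% of calls were higher. The median change over all genes was 0.207, and 0.004 with median ratio rescaling, so small rises can reflect the scaling. With that rescaling 42.8% of 6028 calls were higher and with quantile normalization 64%. Among changes of at least 2-fold, 1324 were higher and 1450 lower. The rises of CASTOR (0.30), SUNN (0.77), EFD (0.63) and NOOT1 (0.51) ended with median ratio rescaling (limma adjusted p = 0.63, 0.18, 0.23 and 0.18) and with quantile normalization (limma adjusted p = 0.26, 0.1, 0.085 and 0.075). They also ended when 1 library was left out. These were A17 replicate 2, 3 or 4 and dnf1-2 replicate 3 or 4 for CASTOR (limma adjusted p = 0.063 to 0.1), and A17 replicate 1, 2 or 3 and dnf1-2 replicate 1, 3 or 4 for SUNN (limma adjusted p = 0.056 to 0.082). For EFD they were A17 replicate 3 or 4 and dnf1-2 replicate 1, 2 or 4 (limma adjusted p = 0.089 to 0.14), and for NOOT1 A17 replicate 2 (limma adjusted p = 0.05). The largest rises among unnamed ids were those of Medtr1g100597 (5.23) and Medtr7g086240 (4.65), and the largest falls those of Medtr0149s0080 (-8.29) and Medtr0115s0030 (-8.06), which were -10.09 and -9.76 without dnf1-2 replicate 3.

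Nodules of nin-16 were set against R108. Leghemoglobins fell from 3.75 ± 0.32% of summed FPKM in R108 to 0.09 ± 0.04% in nin-16 (SD, n = 4 each). NCR169 fell from 613 ± 123 to 1.05 ± 0.798 FPKM, NLP2 from 45 ± 16.7 to 0.117 ± 0.053 FPKM and CLE13 from 55.7 ± 21.8 to 0.819 ± 0.23 FPKM. Some infection genes were higher, such as LYK10, from 2.58 ± 0.941 to 13.2 ± 4.31 FPKM, and ERN2 (Medtr6g029180), from 2.51 ± 0.647 to 10.9 ± 2.27 FPKM. The sugar transporter SWEET11 (Medtr3g098930) rose from 14.3 ± 3.4 to 89.8 ± 20.2 FPKM.

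NIN itself was lower in all 4 nin-16 libraries than in all 4 R108 libraries but did not pass (-0.42, SE 0.21, limma adjusted p = 0.15). With a replicate block within each background it passed (-0.42, limma adjusted p = 0.035), as it did with median ratio rescaling (-0.68, limma adjusted p = 0.023), array weights (limma adjusted p = 0.049) and a fit of the 2 groups alone (limma adjusted p = 0.013). All 11 leghemoglobins fell, with a median of -6.35 (camera adjusted p = 1.1e-20, and adjusted p = 0.011 with an estimated correlation). Of the 9 tested bacteroid genes, 4 fell, 2 rose and 3 did not pass (4 and 2 adjusted over the list alone; camera adjusted p = 0.0015, and adjusted p = 0.035 with an estimated correlation). NCR169 fell by 8.28 (SE 0.48, limma adjusted p = 2.1e-09) and NAD1 fell by 2.35 (SE 0.21, limma adjusted p = 3.9e-07). SYMCRK fell by 1.63 (SE 0.22, limma adjusted p = 4.1e-05) and the metal transporter NRAMP1 (Medtr3g088460) fell by 1.49 (SE 0.20, limma adjusted p = 3.1e-05). SWEET11 rose by 2.57 (SE 0.37, limma adjusted p = 7.8e-05). DNF1 rose by 1.14 (SE 0.42, limma adjusted p = 0.048), higher in all 4 libraries, but the call ended with the replicate block over all nodule groups (limma adjusted p = 0.051), with median ratio rescaling (0.87, limma adjusted p = 0.19), with a pseudocount of 0.1 (limma adjusted p = 0.057), without a filter (limma adjusted p = 0.072) and without any 1 of the 8 libraries (limma adjusted p = 0.058 to 0.11). The DNF1 call held with the replicate block within each background.

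Of the 22 signalling and infection genes, 8 rose, 1 fell and 13 did not pass (8 and 1 adjusted over the list alone; camera adjusted p = 0.41, and adjusted p = 0.78 with an estimated correlation). LYK10 rose by 1.96 (SE 0.29, limma adjusted p = 0.00012), ERN2 by 1.75 (SE 0.22, limma adjusted p = 2.3e-05) and RPG (Medtr1g090807), needed for the growth of infection threads, by 1.22 (SE 0.17, limma adjusted p = 7e-05). IPD3 fell by 0.81 (SE 0.19, limma adjusted p = 0.0044). The rises of NSP1 (0.74), ERN1 (0.60), VPY (1.09), LIN (0.35) and the early nodulin ENOD11 (Medtr3g415670, 0.90) ended with median ratio rescaling (limma adjusted p = 0.12, 0.09, 0.11, 0.58 and 0.09). VPY also ended in a fit of the 2 groups alone (limma adjusted p = 0.064) and without nin-16 replicate 2, 3 or 4 or R108 replicate 1 or 2 (limma adjusted p = 0.056 to 0.092). Of the 12 tested organogenesis regulators, 3 fell, 1 rose and 8 did not pass (3 and 1 adjusted over the list alone). The list passed (camera adjusted p = 0.031) but not with an estimated correlation (adjusted p = 0.3), without NIN (camera adjusted p = 0.055), with quantile normalization (camera adjusted p = 0.05) or with median ratio rescaling (camera adjusted p = 0.077). Its median was 0.03 and its mean -0.79. NLP2 fell by 5.29 (SE 0.38, limma adjusted p = 3.1e-08) and CLE13 fell by 4.89 (SE 0.44, limma adjusted p = 3.8e-07), and the ERF factor EFD (Medtr4g008860) rose by 1.34 (SE 0.24, limma adjusted p = 0.00059). CLE12 (Medtr4g079630) fell by 1.36, a call that ended without nin-16 replicate 3 (limma adjusted p = 0.059) or R108 replicate 1 (limma adjusted p = 0.051). NF-YA1 stood at 233 ± 54.1 FPKM in nin-16 and 168 ± 16.8 in R108 and did not pass (0.44, limma adjusted p = 0.19). It passed with the replicate block within each background (0.44, limma adjusted p = 0.038) and with quantile normalization (0.83, limma adjusted p = 0.032). SYMREM1 stood at 238 ± 50.6 and 250 ± 11.1 FPKM (limma adjusted p = 0.65).

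**Figure D3:**
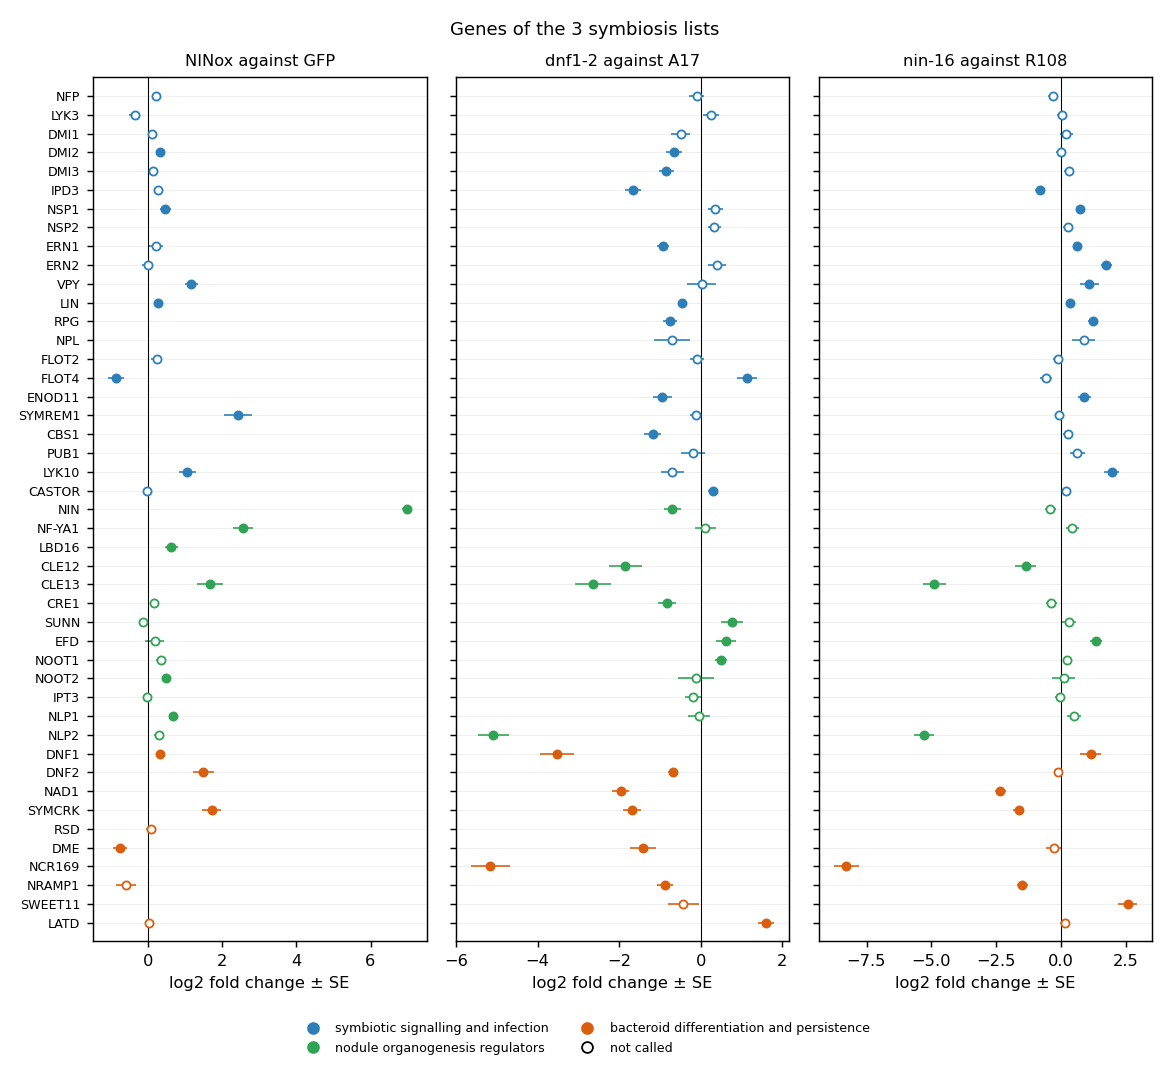
Log2 fold change on the log2(FPKM + 1) scale with its standard error for each tested gene of the 3 symbiosis lists in NINox, dnf1-2 and nin-16, with filled points for genes that passed and open points for those that did not. NCR169 fell by 5.16 in dnf1-2 and fell by 8.28 in nin-16, and LYK10 rose by 1.06 in NINox and 1.96 in nin-16.

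Of the 1016 nodule-restricted genes tested in nin-16, 766 fell, 45 rose and 205 did not pass, with a median of -3.69 (camera adjusted p = 1.5e-144, and adjusted p = 0.00083 with an estimated correlation). Their share of summed FPKM, over the 798 genes of both wild types, fell from 36.74 ± 2.6% in R108 to 6.71 ± 1.25% in nin-16 (SD, n = 4 each). Across all 23450 genes, 5935 were higher and 1879 lower, so that 76% of calls were higher, while 43.4% of 4423 calls were higher with median ratio rescaling. The replicate block within each background gave 9504 calls, 7420 higher and 2084 lower. The median change over all genes was 0.228, and 0.015 with that rescaling. Among changes of at least 2-fold, 938 were higher and 1331 lower. The largest rises among unnamed ids were those of Medtr8g072130 (5.54) and Medtr5g021730 (5.19), and the largest falls those of Medtr2g450280 (-11.20) and Medtr1149s0010 (-10.44).

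The overlap of the mutants and the difference between their effects were tested next. Falls overlapped most: 1156 genes were lower in both mutants, against 184 for independent lists (odds ratio 28.5, 95% interval 25.5 to 31.8). For rises the overlap was 2529 genes against 1781 (odds ratio 2.14, 95% interval 2.01 to 2.28, Fisher's exact test, 2-sided p = 1.1e-127). With median ratio rescaling 419 genes rose in both mutants, out of 2578 rises in dnf1-2 and 1920 in nin-16. The 1781 does not apply to those shorter lists, whose overlap was not tested, so the 419 does not show that the overlap of rises was lost. Fold changes of the mutants correlated across the 23450 genes with Pearson's r 0.67 and Spearman's rho 0.29, over genes that are not independent replicates. Of the 798 nodule-restricted genes, 641 fell in both mutants, with medians of -2.59 in dnf1-2 and -5.00 in nin-16. The control libraries took part in choosing these genes, so the values are descriptive, and the sets chosen in the other wild type had medians of -1.93 and -3.69. Of these 641, the fall was deeper in nin-16 for 341 and deeper in dnf1-2 for 16 (limma, difference of effects), while 284 did not pass that test. The mutants are in different backgrounds, so this ranking cannot be credited to the mutations alone. Replicate 3 of dnf1-2, which held more of these transcripts, bears on this ranking. Without it 626 genes fell in both, of which 353 fell deeper in nin-16, 58 fell deeper in dnf1-2 and 215 did not pass.

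**Figure D4:**
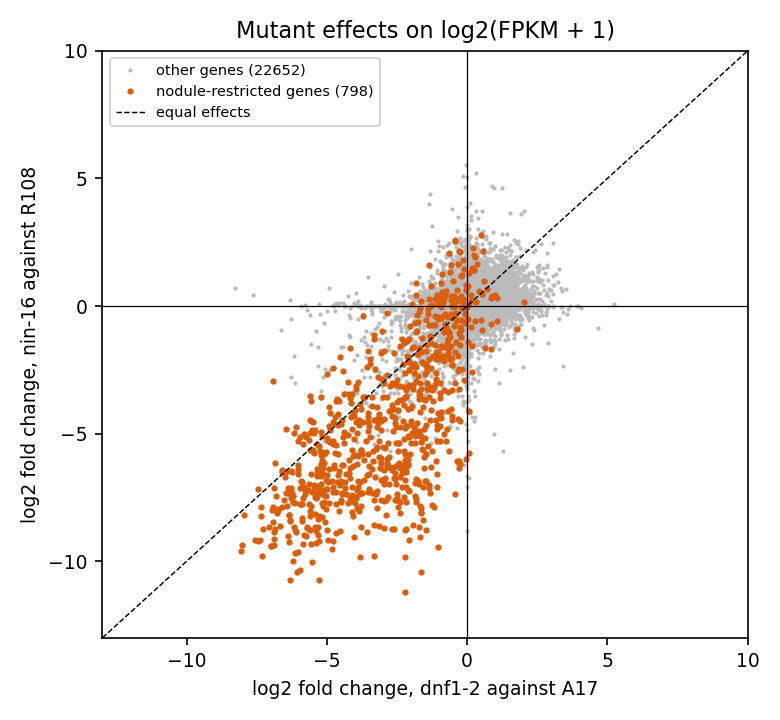
Log2 fold change of every tested gene in dnf1-2 against A17 (x axis) and in nin-16 against R108 (y axis), with the 798 nodule-restricted genes in orange, all other genes in grey and a dashed line at equal effects. Most orange points lie below the dashed line, with medians of -2.59 in dnf1-2 and -5.00 in nin-16.

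The effects of the mutants differed for 3818 genes, 1985 with a higher and 1833 with a lower value in dnf1-2, and part of such calls can come from unequal base levels. The mutants are in different backgrounds, so a difference between the mutations cannot be told apart from a difference between A17 and R108. The count was 2338 among genes at 1 FPKM or more in both backgrounds, 5795 with array weights and 5350 with the replicate block within each background. Of the 22 signalling and infection genes, 9 were relatively lower in dnf1-2, 1 was higher and 12 did not pass (10 and 1 adjusted over the list alone; camera adjusted p = 0.00039, and adjusted p = 0.52 with an estimated correlation). LYK10 differed by -2.65 (SE 0.42, limma adjusted p = 0.00035), RPG by -1.98 (SE 0.25, limma adjusted p = 3.6e-05), ENOD11 by -1.84 (SE 0.33, limma adjusted p = 0.0012) and ERN1 by -1.53 (SE 0.21, limma adjusted p = 0.00011). FLOT4 differed by 1.71 (SE 0.34, limma adjusted p = 0.0026). In the bacteroid list, 2 of 9 were relatively higher in dnf1-2, 3 lower and 4 did not pass (2 and 4 adjusted over the list alone; camera adjusted p = 0.65, and adjusted p = 0.83 with an estimated correlation), among them SWEET11 (-2.99, SE 0.52, limma adjusted p = 9e-04) and LATD (1.45, SE 0.29, limma adjusted p = 0.0026). SWEET11 stood at 16.9 ± 8.9 FPKM in dnf1-2 and 22.8 ± 10.9 in A17 (limma adjusted p = 0.39, and 0.039 with the replicate block within each background), and LATD at 48.7 ± 6.38 in nin-16 and 44.1 ± 9.36 in R108 (limma adjusted p = 0.6). Among organogenesis regulators CLE13 alone differed (2.23, SE 0.62, limma adjusted p = 0.022, 0.051 without A17 replicate 2 and 0.053 with voom), 11 of 12 did not pass (1 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.74, and adjusted p = 0.83 with an estimated correlation), and NIN (-0.28, limma adjusted p = 0.59) and NLP2 (0.20, limma adjusted p = 0.84) were among these. The difference for NLP2, which stood at 0.117 FPKM in nin-16, passed with a pseudocount of 0.1 (2.13, limma adjusted p = 0.043) and with voom (2.95, limma adjusted p = 0.042), and was -0.32 without dnf1-2 replicate 3 (limma adjusted p = 0.53). For leghemoglobins, 4 of 11 fell less in dnf1-2 and 7 did not pass (6 and 0 adjusted over the list alone; camera adjusted p = 0.0015, and adjusted p = 0.61 with an estimated correlation).

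The genes called in NINox roots were then followed in the mutants. Of 3687 genes higher in NINox and tested in nodules, 10.1% were lower in dnf1-2 against 4.3% of other genes (odds ratio 2.51, Fisher's exact test, 2-sided p = 4e-39), and 7.4% were lower in nin-16 against 3.2% (odds ratio 2.42, Fisher's exact test, 2-sided p = 1.3e-27). More of the same genes were higher than lower in the mutants, but fewer than among other genes. In dnf1-2 24.3% were higher against 36.7% (odds ratio 0.553, Fisher's exact test, 2-sided p = 1.4e-48), and in nin-16 20.6% against 28.3% (odds ratio 0.658, Fisher's exact test, 2-sided p = 3.7e-22). These overlaps used calls without rescaling. With median ratio rescaling, rises numbered 2578 in dnf1-2 (from 7036) and 1920 in nin-16 (from 5935), and overlaps of those calls were not computed. The Fisher p-values also treat genes as independent. As a ranked set the genes higher in NINox did not pass (camera adjusted p = 0.18 and 0.67, and adjusted p = 0.64 and 0.88 with an estimated correlation). Genes lower in NINox were higher in both mutants as a set (camera adjusted p = 1.6e-07 in dnf1-2 and 0.0015 in nin-16), but not with an estimated correlation (adjusted p = 0.12 and 0.32).

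The last comparison set the wild types beside each other, where genotype and the mapping of R108 reads to the reference cannot be separated. In R108 nodules 7600 genes were higher and 6416 lower than in A17, and 6883 higher and 7380 lower with median ratio rescaling. Among the list genes, FLOT4 was higher by 1.93 (SE 0.24, limma adjusted p = 6.4e-06) and LATD by 1.91 (SE 0.20, limma adjusted p = 1.1e-06), while DME (-1.68, SE 0.32, limma adjusted p = 0.00037) and NLP2 (-1.65, SE 0.38, limma adjusted p = 0.0017) were lower. Of 22 signalling genes 3 were higher and 6 lower, of 12 organogenesis regulators 2 and 2, of 9 bacteroid genes 2 and 2, and of 11 leghemoglobins 0 and 1, with the same counts adjusted over the list alone except 0 and 0 for leghemoglobins. The calls of SUNN and DMI3 ended without R108 replicate 1 (limma adjusted p = 0.069 and 0.064). EFD ended without A17 replicate 4 (limma adjusted p = 0.06) and in a fit of the 2 groups alone (limma adjusted p = 0.055). IPT3 ended in that fit (limma adjusted p = 0.07), with array weights (limma adjusted p = 0.13) and without A17 replicate 1 or 2 (limma adjusted p = 0.062 and 0.061). No list passed (camera adjusted p = 0.74, 0.94, 0.94 and 0.94, and adjusted p = 0.95 for each with an estimated correlation).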

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

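The tests on dnf1-2 replicate 3 other than the one for an R108 source, and those on carry-over and sequencing depth in NINox roots, were chosen only after the result was seen.

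About 3 in 4 calls were higher in both mutants (75.3% in dnf1-2 and 76% in nin-16). Nodule-restricted genes took 19.4% of reads in A17 and 4.79% in dnf1-2, and 17.94% in R108 and 4.19% in nin-16, which may raise the FPKM of all other genes in the mutants. That loss predicts a shift of 0.24 and 0.22, and the medians of the other genes were 0.22 and 0.24. With the nodule-restricted genes taken out of the library totals, 48.3% and 47.6% of calls were higher, so this explanation can account for the excess. Part of a near-even split follows from the rescaling itself, and true small rises of many genes are not excluded.

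Replicate 3 of dnf1-2 held more of the transcripts lost in the other 3 libraries, with 75.4 FPKM of DNF1, 117 of NCR169, 10.8 of NLP2 and 0.68% of FPKM in leghemoglobins. A possible explanation is A17 nodules or RNA mixed in, since 402 lost genes returned at a median of 0.099 of the A17 level (quartiles 0.082 and 0.12). DNF1 returned at 0.28, outside the middle 95% of these genes (0.035 to 0.19), and the 5 genes high in the other 3 libraries and low in A17 lost a median of 0.36 (quartiles 0.33 and 0.41), so 1 mixed share accounted for neither. An A17 library under a wrong label was ruled out by the upper quartile of 0.12, and an R108 source by a median of 0 over 57 R108 genes. The expectation for this mixture was rewritten after its first form, which tied it to DNF1, was not met, and a partly functional dnf1-2 plant could not be separated from mixed material.

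Nodule-restricted genes in NINox roots (66 of 798) could come from NIN or from carried-over nodule RNA. Carry-over from A17 nodules at 1 share (0.355%) would keep their order of abundance, but 32 of the 50 genes most abundant in A17 stood at under 0.1 of the level that share gives. Deeper sequencing did not account for them, since a NINox library was at most 1.37 times as deep as a GFP library but held at least 25 times the reads on these genes (15593 to 38027 against 281 to 623). The choice of genes fixed the low GFP side of that ratio but, apart from NIN, not the NINox side. NIN itself is among the 798 genes and among the 66, so construct reads are part of the share and of these counts. Values without NIN were not computed. Carry-over from R108 or mutant nodules, or from 1 kind of nodule cell, was not tested.

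Among 95 groups of 4 libraries, 10 held a library far from the rest, where chance alone flags about 1 group in 20. Besides the 4 values of dnf1-2 replicate 3 given above, these were ERN2 in dnf1-2 replicate 1 (2.97 FPKM), FLOT4 in dnf1-2 replicate 4 (217), LYK10 in nin-16 replicate 1 (6.79), NIN in nin-16 replicate 3 (61.9), NIN in R108 replicate 4 (93.7) and NCR169 in NINox replicate 1 (0.0758). The NCR169 value is close to the level of 1 read, which was 0.0434 FPKM in a gene of 1 kb in that library. The flags are not independent, as 4 of the 10 came from dnf1-2 replicate 3.

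The 2 mutant effects, each in its own background, differed for 20 genes of the lists. Lower in dnf1-2 relative to nin-16 were DNF1 (-4.66), SWEET11 (-2.99), LYK10 (-2.65), RPG (-1.98), ENOD11 (-1.84), ERN1 (-1.53), CBS1 (-1.45), ERN2 (-1.35), DMI3 (-1.13), IPD3 (-0.86), LIN (-0.82) and DNF2 (-0.57). Higher were NCR169 (3.12), CLE13 (2.23), FLOT4 (1.71), LATD (1.45) and the leghemoglobins Medtr5g081000 (5.46), Medtr1g049330 (4.44), Medtr1g011540 (3.59) and Medtr1g090810 (1.77). The calls of IPD3 and DNF2 ended without any 1 of several libraries (limma adjusted p = 0.053 to 0.086 and 0.05 to 0.073) and without a filter (limma adjusted p = 0.052 and 0.057). IPD3 also ended with the replicate block (limma adjusted p = 0.059) and DNF2 with median ratio rescaling (limma adjusted p = 0.054). With voom, ERN2, CLE13 and Medtr1g011540 ended (limma adjusted p = 0.055, 0.053 and 0.066), and CLE13 also ended without A17 replicate 2 (limma adjusted p = 0.051).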

How the results depend on the processing

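Counts of called genes changed with the settings, and the cause was not tested. The named results were chosen in part for being called or for a large change, so how often they held follows partly from that choice. Of the alternatives for 162 named gene results, 2833 kept the result, 132 ended a call, 20 added one and 10 turned an uncalled direction. Of those for gene lists 445 kept it, 12 ended a call, 6 added one and 7 turned an uncalled direction. Leaving out 1 library gave 3861 to 7234 calls for NINox against GFP (6665), 7217 to 9144 for dnf1-2 against A17 (9338), 6008 to 7043 for nin-16 against R108 (7814), 2895 to 4776 for the difference of effects (3818) and 12794 to 13729 for R108 against A17 (14016). A change of at least 2-fold left 740, 2774, 2269, 2328 and 6688 calls, in the same order. Median ratio rescaling gave 6028 calls in dnf1-2, 4423 in nin-16 and 1854 shared calls, against 3685. For the difference of effects, array weights gave 5795 calls and genes at 1 FPKM or more in both backgrounds 2338. Of 13 gene list tests that passed, among them that of leghemoglobins in NINox, whose outcome the filter fixed, 6 passed with an estimated correlation, as did 0 of 2 for the genes called in NINox. NIN in nin-16, uncalled at -0.42 (-0.46 to -0.33 without 1 library), was called with median ratio rescaling (-0.68), array weights (-0.44), a fit of its own groups and a block within each background (-0.42 for both). Directions of uncalled genes turned for SYMREM1 with quantile normalization (0.33 in dnf1-2, from -0.12, and 0.33 in nin-16, from -0.09), for NF-YA1 in dnf1-2 with median ratio rescaling (-0.14, from 0.12), for SWEET11 in dnf1-2 with array weights (0.16, from -0.42) and for LATD in nin-16 with median ratio rescaling (-0.11, from 0.16). Without 1 library, NF-YA1 in dnf1-2 ran from -0.05 to 0.29, SYMREM1 in nin-16 from -0.23 to 0, and NLP2 in the difference of effects from -0.32 to 0.38. NLP2 there passed with a pseudocount of 0.1 (2.13) and with voom (2.95). Directions of uncalled lists turned for NINox-higher genes in nin-16 with quantile normalization or without a filter (camera adjusted p = 0.78 and 0.36), for organogenesis regulators in the difference of effects with a pseudocount of 0.1 (camera adjusted p = 1), for bacteroid genes there without DNF1 (camera adjusted p = 0.85), and for bacteroid genes in R108 against A17 without A17 replicate 2 or R108 replicate 1 or 2 (camera adjusted p = 0.95, 0.98 and 1, and 0.87 to 1 over all libraries left out). Same-numbered libraries correlated only weakly between A17 and dnf1-2 (0.11, 0.13, 0.08 and 0.05) and between NINox and GFP (0.08, 0.02 and 0.10). Of these, 1 dnf1-2 library and 2 GFP libraries matched their own number best, so weak pairing is not excluded. Between A17 and R108 the correlations were -0.25, -0.09, -0.09 and -0.34, so a block over all nodule groups does not match the pairing. That block ended EFD in dnf1-2 and IPD3 in the difference of effects, and the block in roots ended LBD16 in NINox. Besides DNF1 with the block over all nodule groups, and NIN and NF-YA1 with the block within each background, blocks changed no call of named genes or lists in nin-16 against R108.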

Other observations

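Genes changed in NINox roots often carried neighbouring ids. Among the 379 genes at least 2-fold lower in NINox, 69 pairs were neighbours by id number, against a mean of 6.43 for random sets (permutation test, p = 1e-04, the smallest that 10000 draws can give). The 2 ids with the largest falls, Medtr2g438540 and Medtr2g438560, stand next to each other among the tested ids. Neighbouring pairs also numbered 61 among the 361 genes at least 2-fold higher in NINox (mean for random sets 5.8). They numbered 214 among the 867 genes at least 2-fold lower in both mutants (31.2) and 10 among the 198 at least 2-fold higher in both (1.61). Tandem copies that share reads or regulation could explain such pairs, which the count of 69 does not separate. This test was chosen after the pattern was seen.

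A hypothesis for the nodule mutants is that NLP2 and leghemoglobin loss goes together with the stage that bacteroids reach. NLP2 fell by 5.09 in dnf1-2 and fell by 5.29 in nin-16, and leghemoglobins fell with medians of -5.14 (-5.99 without dnf1-2 replicate 3) and -6.35. The near-equal falls of NLP2 depend on the pseudocount of 1, as levels went from 137 to 4.06 FPKM in dnf1-2 and from 45 to 0.117 FPKM in nin-16, and with a pseudocount of 0.1 or voom they differed by 2.13 or 2.95 (limma adjusted p = 0.043 and 0.042). A test would be a time course of NLP2 and leghemoglobin transcripts in both mutants and in 1 shared background. Another hypothesis is that infection, relative to the own wild type, is more active in nodules of nin-16 than in those of dnf1-2. Of 22 signalling and infection genes, 9 were relatively lower in dnf1-2, among them LYK10 (-2.65), RPG (-1.98), ENOD11 (-1.84) and ERN1 (-1.53). Against this hypothesis, FLOT4 differed in the other direction (1.71), 12 of 22 did not pass, such as SYMREM1 (-0.03) and FLOT2 (0.02), and the list did not pass with an estimated correlation (camera adjusted p = 0.52). Counts of infection threads in sections of both mutants and both wild types would test this. The mutants are in different backgrounds, so such counts would not tell mutation from background.

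The labelled groups were set against other splits of the same libraries, namely all 35 for each pair of groups and 100 drawn at random, the labelled 1 included, for the difference of effects and the shared calls. The labelled split was the only 1 of 35 with as many calls for NINox against GFP (6665, highest other 1397), for dnf1-2 against A17 (9338, highest other 1232), for nin-16 against R108 (7814, highest other 772) and for R108 against A17 (14016, highest other 19). For nin-16 against R108, the 772 came from numbers 1 and 2 set against 3 and 4, that is from the pairing, and within the 8 splits that part every pair the highest other was 0, so pairing leaves the labelled split as 1 of 8. For shared calls it was the only 1 of 100 (3685, highest other 2). Shared calls need calls in both backgrounds, and no other draw kept both as labelled. Unrelated mutant effects would have given the same outcome, so this does not bear on whether the overlap exceeds chance. For the difference of effects 4 of 100 splits, the labelled 1 included, had as many calls (3818, highest other 5651). The 3 others each kept 1 background as labelled, and the 93 splits with neither as labelled reached at most 128.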
